A study of Homo sapiens with 4 samples.

How the data were processed

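The series holds 4 RNA sequencing libraries from the human embryonic stem cell line H1, 1 each from undifferentiated cells and from APLNR+ cells on day 2, CD31+CD34+ cells on day 4 and CD31+CD43+ cells on day 7 of stepwise culture towards blood. Per the labels' protocols, the differentiated populations were sorted by flow cytometry, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit from 2 ug of total RNA.

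The deposited values are a normalised expression signal per gene, 1 table per library, with 2 decimals. Per the submitters' processing notes, BWA, Bowtie and RSEM were used with the genome build hg19; their versions, roles and order, the annotation, and whether counting used strand are not given in the sources used here. Which RSEM measure the authors deposited, FPKM or TPM, is not stated either. The sums differ between libraries, so the tables are not complete TPM tables, and values were compared as deposited, with other scalings as alternatives. Low values showed no steps of whole reads, so depth is unknown and no counting interval or floor is given. Without stated strand, overlapping and antisense genes cannot be told apart, and members of near-identical families (globin pairs, HSPA1A and HSPA1B, ribosomal proteins, histones) share reads.

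Each table had 17634 rows under the same gene symbols. In 28 rows a symbol had been turned into a date; 4 of these, which shared 2 names, were left out, leaving 17630 genes, of which 516 were at 0 in every library, 12075 at 1 or more in any library and 8174 at 5 or more. A value of 0 is reported as listed at 0, with no fold against it.

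With 1 library per group, differences were described by size. The log2 difference of (value + 1) was taken for the 3 successive comparisons and for hESC against HPC, and a gene counted as higher or lower at a log2 difference of at least 1 in size with 5 or more in the higher library. A gene counted for 1 library in particular when its value + 1 there was at least 2 times that in each other library and its value 5 or more. There were 33 gene lists: sort antigens, pluripotency, primitive streak, early mesoderm, endothelial, arterial, venous and lymphatic, haematopoietic transcription factors, pan-leukocyte, erythroid, megakaryocyte, myeloid, lymphoid, definitive endoderm, neural ectoderm, trophoblast and amnion, cardiomyocyte, smooth muscle and mesenchyme, epithelial junction, mesenchymal transition, WNT, BMP, activin and NODAL, and FGF and ERK targets, NOTCH pathway, HOXA, HOXB, DNA methylation enzymes, cell cycle, immediate early and heat shock, glycolysis, antigen presentation and housekeeping. Members at 1 or more in any library counted as detected. A member detected through 1 library alone can only be higher there, so medians and percentiles of stage lists partly follow from this rule. For lists with 3 or more of these, the median difference was placed among 10000 random lists of the same size matched on deciles of mean expression; a list stood outside the central 95% at percentile 2.5 or below, or 97.5 or above.

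Genes were named by rule: the sort antigens; for each successive comparison the 8 largest differences in each direction among genes at 10 or more in the higher library, leaving out small RNA genes and sex-linked markers; for each list up to 4 members with the largest differences and the largest going the other way; and the 5 highest values of each library. Other genes are said to be chosen after their values were seen.

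GC content and length were medians over protein-coding transcripts of GENCODE 29, matched by symbol or by a unique RefSeq synonym for 17437 genes (98.9%). That annotation is of another build than hg19, so no coordinates are printed. The GC trend of a library was the median log2 deviation from each gene's mean in 50 GC bins of genes with a mean of 5 or more, averaged over 5 neighbouring bins, and was divided out; afterwards the rho with GC content from MES to HEP was 0.13. Alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 20, a fold of 4, and members at 5 or more. Others were median-of-ratios and upper quartile scaling, and rescaling without mitochondrial, ribosomal protein and globin genes. The last left these genes out and scaled the other genes of each library back to that library's own sum, so it put the libraries on no common scale. Rescaling each library to a common total and removing the GC trend were added after the data were seen.

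The procedure was tested on simulated data, the hESC values against a copy with log2 noise of SD 0.2 and 200 genes changed 4-fold among 17630. It found 200 of the 200, with 0 unchanged genes called. With a trend of 0.5 per 10 points of GC content added it found 196 and called 61 unchanged genes, and after correction 200 and 0. The slope from MES to HEP in the data was steeper, 0.98 per 10 points over all genes. The changed genes were also planted without regard to GC content. The simulation therefore does not show how well the correction works on these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.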

Results

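Messenger RNA was profiled in H1 human embryonic stem cells and in 3 populations sorted while these cells were taken towards blood in culture. The 4 groups were undifferentiated cells (hESC), APLNR+ mesoderm-stage cells sorted on day 2 (MES), CD31+CD34+ cells sorted on day 4 (HEP) and CD31+CD43+ cells sorted on day 7 (HPC). The cells received activin A at 40 ng/ml with BMP4 at 50 ng/ml for 2 days, then VEGF at 40 ng/ml with bFGF at 50 ng/ml for 2 days, and then the latter pair of factors with SB-431542, an inhibitor of activin and NODAL receptors, for 3 days. Each group was 1 library, so no value has a replicate error, no test across samples was possible and no difference between populations has a replicate check. The sequencing depth behind the values is unknown. Differences are given as log2 differences of (value + 1), a scale that understates the change of genes with low values, and genes are counted as higher or lower by a fixed rule of size (at least 2-fold on that scale, with 5 or more in the higher library).

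Of 17630 genes analysed, 6639 stood at 5 or more in hESC, 6655 in MES, 5191 in HEP and 5246 in HPC. The values summed to 426980 in hESC, 363396 in MES, 306724 in HEP and 352604 in HPC. Ribosomal protein genes made up 28.8% of the sum in hESC, 23.7% in MES, 19.1% in HEP and 30.0% in HPC, and histone cluster genes 9.62%, 14.3%, 18.6% and 15.7%. The highest values belonged mostly to the translation machinery: RPL37A led in hESC (5460), MES (3797) and HPC (4667), with EEF1A1, RPL41 and RPS18 also among the 5 highest in these 3 libraries, RPS27 in hESC and RPL9 in HPC. In HEP the highest were TMSB10 (3788), an actin-binding peptide that was also among the 5 highest in MES, the myosin light chain MYL6 (2523), RPL37A (2428) and the histone genes HIST2H4A and HIST2H4B, which carry one value (2394) and cannot be told apart. Reads shared with near-identical copies also leave the split between single ribosomal protein genes uncertain.

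The antigens used for the sorts were read first, as a check of the labels. APLNR, the apelin receptor, stood at 0.57 in hESC, 344 in MES, 250 in HEP and 15.6 in HPC. CD34 stood at 0.13, 1.35, 43.6 and 18.4 in the same order, and SPN, which encodes CD43, at 0.11, 0.08, 0.97 and 24.4. PECAM1, which encodes CD31, was at 0.01 in hESC and MES, 1.83 in HEP and 7.49 in HPC, and so was low in both libraries sorted for it.

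Across the 17114 genes above 0 in any library, the closest pairs were HEP and HPC (Spearman rho 0.928 across genes, which are not independent replicates) and hESC and MES (0.918). The lowest rho was that of hESC and HEP (0.827), next to that of hESC and HPC (0.828); with the trend with GC content removed, as described next, the lowest was that of hESC and HPC (0.843). Genes standing at least 2-fold above each of the other 3 libraries numbered 466 in hESC, 315 in MES, 184 in HEP and 237 in HPC; with that trend removed they numbered 241, 249, 165 and 275, of which 222, 216, 128 and 223 were also found in the values as deposited.

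The differences between libraries followed the GC content of the transcripts. From MES to HEP the Spearman rho of the log2 difference with GC content was 0.71 across 6375 genes with a mean of 5 or more. The median difference was -1.87 in the tenth of these genes with the lowest GC content (quartiles -2.35 and -1.39) and 0.49 in the tenth with the highest (quartiles 0.10 and 0.88). The rho was 0.22 from hESC to MES, -0.43 from HEP to HPC and 0.53 from hESC to HPC. Counts are therefore also given after this trend was removed from each library, an alternative chosen after the data were seen. The removal takes out a library's median deviation in every GC bin, so it also rescales the libraries to a common median level.

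**Figure D1:**
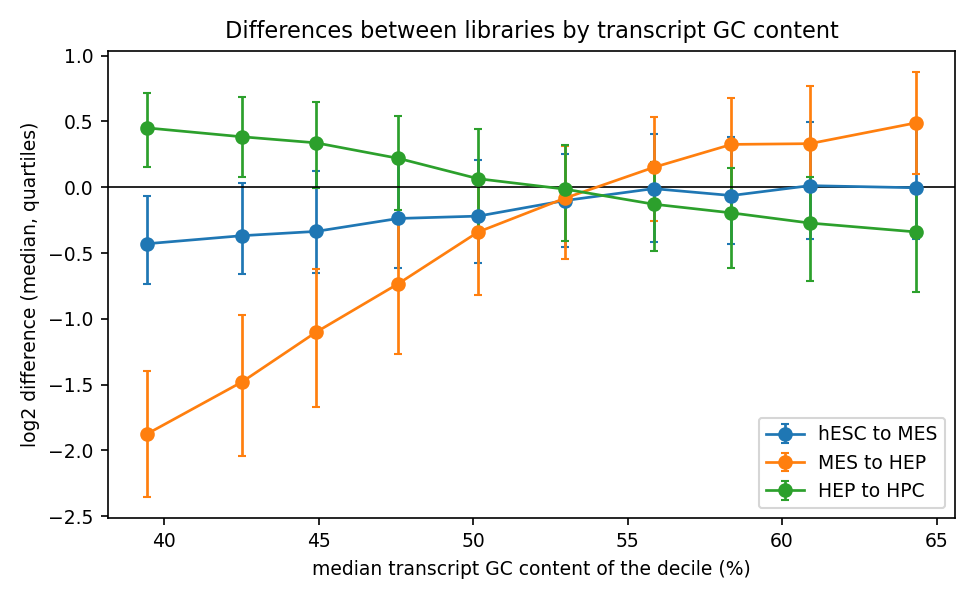
Median log2 difference of (value + 1) between successive populations (y axis) for 10 groups of genes ordered by transcript GC content in percent (x axis); bars span the quartiles of genes, not replicates. From MES to HEP the medians run from -1.87 at the lowest GC content to 0.49 at the highest, and from HEP to HPC they run the opposite way.

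The comparison of hESC with MES covers the first step, under activin A and BMP4. Many genes of the primitive streak (8 of 14) and of early mesoderm (13 of 22) were higher in MES, and many genes of the pluripotent state (13 of 20, or 10 of 20 with the GC trend removed) were lower. CER1, a secreted antagonist of NODAL and BMP, went from 1.92 to 2761, the largest difference of any gene at 10 or more in either library (log2 difference 9.89), and APLNR, the sort antigen, came next (7.78). The others of the 8 largest were the neuropeptide gene GRP (0.06 to 117), the retinoic acid hydroxylase CYP26A1 (0.98 to 140), the hyaluronan synthase HAS2 (1.92 to 186), the early mesoderm transcription factor MESP1 (0.12 to 65.9), the growth factor BMP2 (0.62 to 95.7) and the microfibril gene MFAP4 (0.37 to 77.9). In the other direction, SOX2, a core pluripotency transcription factor, went from 56.7 to 0.41 (-5.36), followed by the deubiquitinase USP44 (86.6 to 1.77), the calcium sensor VSNL1 (26.8 to 0.34), the WNT antagonist SFRP1 (71.1 to 3.24), LECT1 (77.6 to 4.16), the tyrosine kinase LCK (71.9 to 4.76), the receptor phosphatase PTPRZ1 (26.5 to 1.31) and ZDHHC22 (14.9 to 0.41).

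Of 14 detected primitive streak genes, 8 were higher and 0 lower in MES, with a median log2 difference of 3.24. MIXL1 went from 0.04 to 57.2 and EOMES from 0.07 to 56.5, while GSC, listed at 0 in hESC, reached 23.1; FOXH1 went the other way without passing the rule (14.7 to 11.4). Of 22 early mesoderm genes, 13 were higher and 0 lower (median 2.82), among them BMP4 (0.93 to 102) and HAND1 (0.07 to 47.1), and GATA6 went from a listed 0 to 35.1. Of 20 pluripotency genes, 13 were lower and 1 was higher (median -1.38, or -1.18 with the GC trend removed); TERF1 went from 91.5 to 8.25 and PRDM14 from 23.6 to 2.40. The 3 medians lay at percentiles 100, 100 and 0 among 10000 random lists matched on mean expression, a description of these libraries and no p-value.

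Targets of the 2 signals added in this step, BMP and activin, were mostly higher in MES. Of 10 BMP targets, 8 were higher and 0 lower (median 2.88), among them MSX2 (0.17 to 21.4), BAMBI (14.4 to 147) and ID2 (7.96 to 75.5). Of 10 activin and NODAL targets, 6 were higher and 0 lower (median 1.26), including LEFTY2 (2.16 to 11.9). Of 9 WNT targets, for which the protocol names no added factor, 4 were higher and 0 lower (median 2.03), including DKK1 (0.08 to 40.2) and LGR5 (0.03 to 14.3). FGF and ERK targets lay within the central 95% of random lists (1 of 10 higher, 3 lower, percentile 60.1). So did the NOTCH pathway (1 of 13 higher, 1 lower, percentile 96.9), but not with a pseudocount of 0.1 (99.1) or over members at 5 or more (98.7).

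Genes of the mesenchymal transition and of epithelial junctions moved apart. Of 10 mesenchymal transition genes, 8 were higher and 0 lower (median 2.95), including fibronectin, FN1 (12.2 to 158), vimentin, VIM (34.2 to 345), and SNAI2 (0.15 to 10.2). Of 17 epithelial junction genes, 8 were lower and 2 higher (median -1.24): CLDN7 went from 44.6 to 10.7 and EPCAM from 46.3 to 13.1, whereas the keratin KRT8 went from 218 to 666. Some markers of other cell types were higher in MES. Of 6 cardiomyocyte genes 4 were higher (median 3.01), led by the atrial myosin light chain MYL7 (0.65 to 69.4), and of 14 smooth muscle and mesenchyme genes 7 were higher and 1, THY1 (76.8 to 14.1), was lower (median 1.34). Of 8 definitive endoderm genes 2 were higher, CER1 and SOX17 (0.19 to 25.1), and 0 lower (median 0.97). Of 5 trophoblast and amnion genes 1, TFAP2C (0.37 to 5.12), was higher, with KRT7 at 4.06 and 0.96 (median 1.51), and of 2 detected neural ectoderm genes, too few for a median, OTX2 went from 10.1 to 25 and SOX3 from 4.01 to 0.20. Immediate early and heat shock genes, which dissociation and sorting can induce, were higher in 7 of 14 cases and lower in 0 (median 1.03), among them IER3 (8.47 to 158) and FOS (4.00 to 56.3). The heat shock genes HSPA1A (49.2 to 77.6), HSPA1B (58.6 to 69.7) and DNAJB1 (25.6 to 23.8), looked at after their values were seen, did not pass the rule. A sort is stated for MES and not for hESC, so sorting and differentiation cannot be told apart here.

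Blood and vessel genes were mostly low at this step. None of 19 haematopoietic transcription factors passed the rule (percentile 94.5, but 99.6 with a pseudocount of 0.1), with GATA2 at 0.07 and 3.36. Of 25 endothelial genes 2 were higher and 1 lower (0 lower with the GC trend removed; percentile 73.4), with KDR, the VEGF receptor, at 24.5 and 62.4. Of 14 arterial genes 3 were higher (median 0.43, percentile 98.8): NRP1 (0.55 to 14.7), CXCR4 (0.80 to 6.24) and SOX17, which is also on the definitive endoderm list. With the GC trend removed 2 were higher and the percentile was 97.6, next to the bound. The 7 HOXB genes had a median of 0.98 (percentile 99.7, but 95.1 over members at 5 or more) although none passed the rule. The venous and lymphatic (percentile 45.0), pan-leukocyte (36.2), erythroid (78.0), megakaryocyte (69.0), myeloid (68.8), lymphoid (49.0), cell cycle (71.0), glycolysis (97.0), DNA methylation (73.9), antigen presentation (11.3) and housekeeping (51.8) lists lay within the central 95% of random lists. So did the sort antigens (94.3, but 98.7 with a pseudocount of 0.1). Single members of these lists did pass the rule, such as DNMT3B, the de novo DNA methyltransferase (430 to 74.7).

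By the rule of size 669 genes were higher and 653 lower in MES than in hESC. The share of higher genes, 50.6%, depended on the scaling. It was 65.1% with median-of-ratios scaling (781 higher, 419 lower), 68.0% with each library rescaled to a common total (1468 and 690) and 65.0% with the GC trend removed (714 and 385). Rescaling without mitochondrial, ribosomal protein and globin genes gave 41.5% (711 and 1002). That step returns each library to its own sum, not to a common scale. It raises hESC more than MES, since ribosomal protein genes made up more of the sum in hESC. Median-of-ratios scaling raised the log2 ratios of the values to hESC by 0.16 in MES, 0.27 in HEP and 0.29 in HPC. The rise was less on the scale of (value + 1) for low values. Each gene among the 8 largest in either direction kept its call with that scaling, with upper quartile scaling and with the GC trend removed. These genes were chosen for differences far larger than such shifts, so their calls say little about smaller differences.

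**Figure D2:**
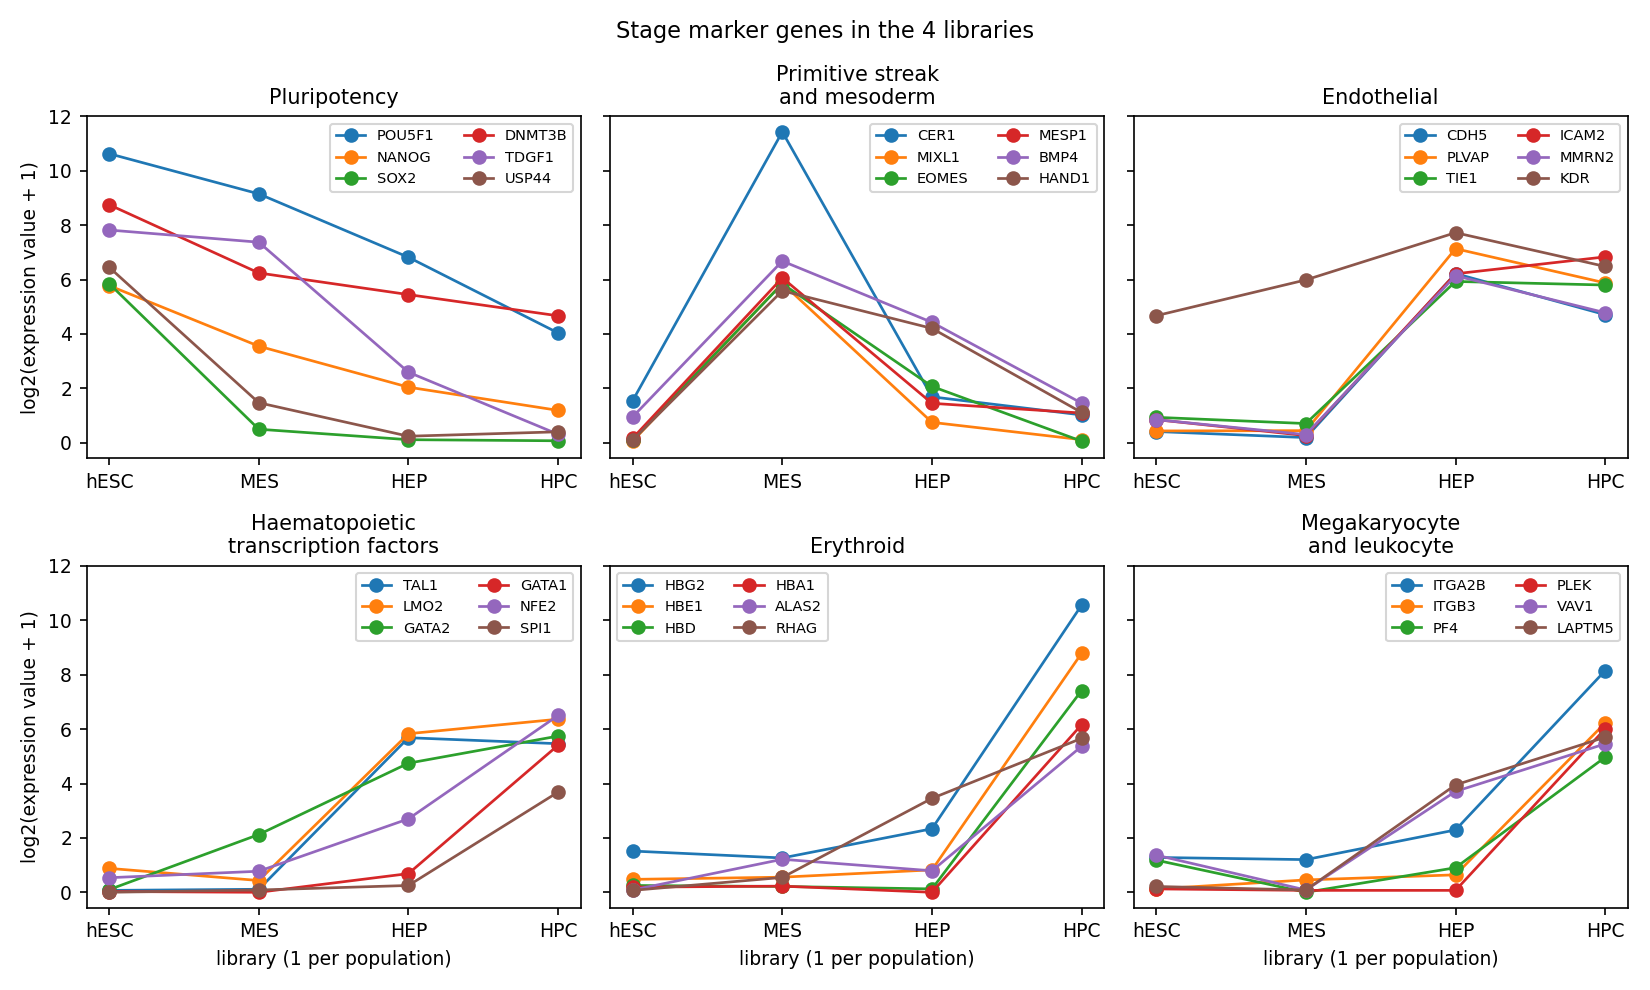
Values of marker genes as log2(value + 1) (y axis) in the 4 libraries in order of differentiation (x axis), 1 point per library, in 6 panels by gene group. SOX2 stands at 56.7 in hESC and 0.41 in MES, CER1 is highest at 2761 in MES, CDH5 reaches 73.5 in HEP, and HBG2 stands at 1509 in HPC.

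The comparison of MES with HEP covers the step under VEGF and bFGF. Most endothelial genes (20 of 25) and some transcription factors of blood formation (9 of 19) were higher in HEP, and many genes of the primitive streak (9 of 14) were lower. PLVAP, a protein of endothelial diaphragms, went from 0.36 to 140 (log2 difference 6.69), followed by the G protein subunit GNG11 (6.81 to 608), VE-cadherin, CDH5 (0.14 to 73.5), the adhesion molecule ICAM2 (0.20 to 73.2), the endothelial matrix gene MMRN2 (0.23 to 69.6), TAL1, a transcription factor required for blood formation (0.08 to 50.4), and the ficolin FCN3 (0.14 to 51.0). EXOC3L1, listed at 0 in MES, stood at 44.0. The lower genes were led by CER1 (2761 to 2.22, -9.74), GRP (117 to 0.58), MFAP4 (77.9 to 0.75), MIXL1 (57.2 to 0.68), L1TD1 (75.9 to 1.43), CNKSR3 (69.9 to 1.35), the fatty acid binding protein gene FABP5 (497 to 16.9) and the NODAL co-receptor TDGF1 (165 to 5.03).

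Of 25 endothelial genes, 20 were higher and 0 lower in HEP, with a median of 3.28. Of 14 arterial genes 6 were higher and 1, EFNB2 (6.16 to 2.53), was lower (median 1.01; 9 higher, 0 lower and a median of 1.62 with the GC trend removed), with the gap junction gene GJA4 at 1.48 and 20.5 and the NOTCH ligand DLL4 at 0.22 and 7.54. Of 4 venous and lymphatic genes 2 were higher (median 1.11; 1 with the GC trend removed), including FLT4 (0.92 to 18.1). The NOTCH pathway, which shares members with the arterial list, had 5 of 13 higher and 0 lower (median 0.96; 7 higher with the GC trend removed), with JAG2 at 0.98 and 14.2. Of 19 haematopoietic transcription factors 9 were higher and 0 lower (median 1.51; 11 higher with the GC trend removed), among them LMO2 (0.35 to 56.0), GFI1 (0.14 to 19.1) and LYL1 (1.27 to 38.1). Of 14 pan-leukocyte genes 3 were higher, LAPTM5 (0.06 to 14.5), VAV1 (0.06 to 12.1) and ARHGDIB (0.21 to 12.9), and LCP1 was lower (7.55 to 2.88), though not with the GC trend removed (log2 difference -0.31). All these medians lay above percentile 97.5.

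Of 14 primitive streak genes, 9 were lower and 0 higher in HEP (median -1.94), and of 10 activin and NODAL targets 8 were lower and 0 higher (median -2.18), including LEFTY1 (19.9 to 0.85) and NODAL (7.36 to 0.33). Pluripotency genes were lower in 10 of 20 cases and higher in 0 (median -1.37; 7 lower, median -0.80, with the GC trend removed). Of 22 early mesoderm genes 10 were lower, among them MESP1 (65.9 to 1.73) and PDGFRA (15.5 to 1.68), and KDR was higher (62.4 to 210). The list's median of -0.93 lay at percentile 1.93, but at percentile 13.6 with a pseudocount of 0.1 and 4.75 over members at 5 or more. With the GC trend removed the median was -1.24, at percentile 0, with 11 lower and 1 higher. Immediate early and heat shock genes were lower in 6 of 14 cases and higher in 2 (median -1.04, percentile 2.41), with GADD45B at 48.4 and 4.72. This call did not hold with a pseudocount of 0.1 (percentile 6.14), over members at 5 or more (4.29) or with median-of-ratios scaling (2.56). It did hold with the GC trend removed (8 lower, 1 higher, median -1.12, percentile 0).

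Antigen presentation genes were higher in 4 of 8 cases and lower in 0 (median 1.21), with HLA-E at 10.1 and 69.9 and the peptide transporter TAP1 at 1.53 and 12.4. Of 14 smooth muscle and mesenchyme genes 5 were higher, including COL3A1 (1.05 to 23.1), and 2 lower, including POSTN (27.5 to 0.55), with a median of 0.94; 4 were lower with the GC trend removed. HOXB genes had a median of 1.16, with 1 of 7, HOXB2 (1.69 to 5.02), higher; with the GC trend removed it was at 0.97 on the log2 scale and 0 of 7 passed. The lymphoid list (median 0.70) had 1 of 4 members higher, CD79B (1.80 to 30.2), and the megakaryocyte list (median 0.30) had none of 13. The myeloid median of 0.16, at percentile 98.8, came with no member past the rule and lay at percentile 86.7 with the GC trend removed and 94.2 over members at 5 or more. Within the central 95% lay the erythroid (percentile 95.6), definitive endoderm (84.0), trophoblast and amnion (35.3), cardiomyocyte (78.0), mesenchymal transition (93.4, but 99 over members at 5 or more), BMP target (40.8), DNA methylation (34.4), glycolysis (35.3) and housekeeping (67.1) lists. The epithelial junction (7.54), WNT target (35.7) and FGF and ERK target (96.9) lists did too, but with the GC trend removed they lay at percentiles 0.11, 0.63 and 98.9, and the WNT targets at 0.48 over members at 5 or more. Of the neural ectoderm genes, OTX2 was lower (25 to 2.53).

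The cell cycle list was lower in 8 of 24 cases and higher in 0 (median -0.77, percentile 1.16), with CDK1 at 101 and 11.8 and TOP2A at 49.1 and 5.85. With the GC trend removed its median was -0.12, at percentile 19.0, with 3 members lower. By the rule of size 584 genes were higher and 2448 lower in HEP than in MES. With the GC trend removed 642 were higher and 862 lower; 418 and 783 genes passed both ways. Upper quartile scaling gave 1367 higher and 1506 lower, a share of higher genes of 47.6% against 19.3% as deposited and 42.7% with the GC trend removed. Other scalings kept a large excess of lower genes. The share of higher genes was 23.7% with median-of-ratios scaling (704 higher, 2264 lower) and 28.3% with each library rescaled to a common total (1251 and 3163).

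**Figure D3:**
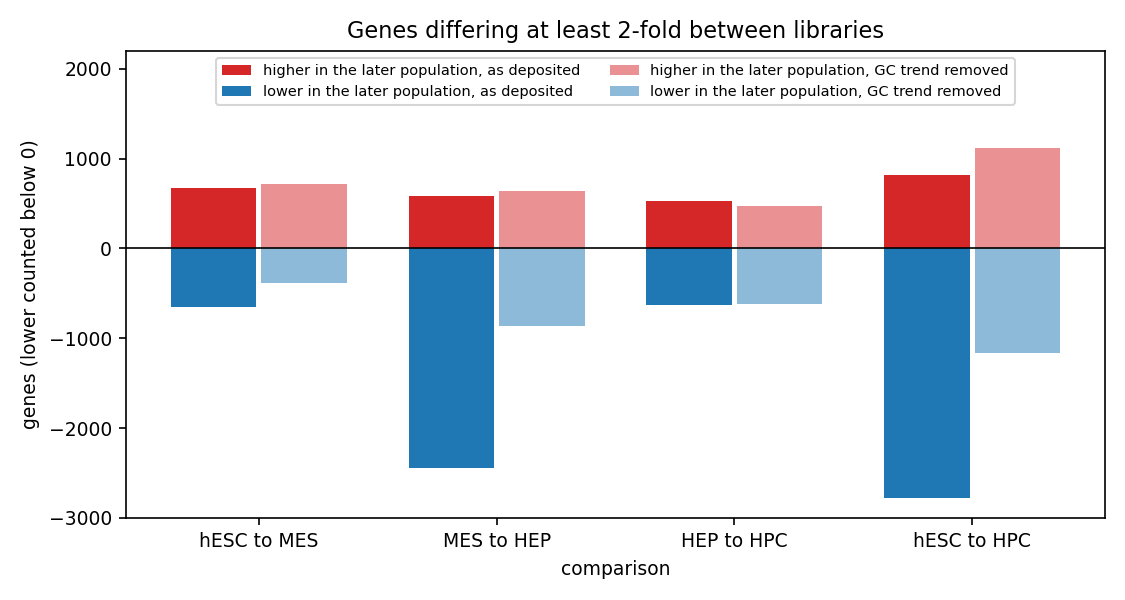
Number of genes higher (above 0) and lower (below 0) in the later population of each comparison (x axis) by the rule of size, as deposited (dark bars) and with the GC trend removed (pale bars). From MES to HEP the lower genes number 2448 as deposited and 862 with the trend removed, a step that also rescales the libraries to a common median level.

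The comparison of HEP with HPC covers the last step, in which SB-431542 was added. Most erythroid (13 of 19) and pan-leukocyte (11 of 14) genes and some megakaryocyte genes (6 of 13) were higher in HPC, and many endothelial (13 of 25) and mesenchymal transition (6 of 10) genes were lower. The fetal globin genes HBG2 (4.05 to 1509, log2 difference 8.22) and HBG1 (1.24 to 655) led, followed by the embryonic globin HBE1 (0.77 to 442) and HBD (0.09 to 170). HBA1 and HBA2, both listed at 0 in HEP, stood at 70.8 and 51.0; reads shared between HBA1 and HBA2, and between HBG1 and HBG2, leave the split within each pair uncertain. PLEK, a platelet and leukocyte protein kinase C substrate, went from 0.05 to 63.5 and the platelet integrin ITGA2B from 3.90 to 283. The lower genes were led by the BMP and WNT antagonist SOST (40.6 to 0.53), the cystatin CST1 (96.6 to 2.70), PRR9 (24.6 to 0.08), the tyrosine kinase ZAP70 (58.9 to 1.69), cardiac actin, ACTC1 (54.6 to 1.71), ADAMTSL2 (26.9 to 0.40), the transcription factor SP6 (75.4 to 2.86) and APLN, which encodes the ligand of APLNR (22.0 to 0.22).

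Of 19 erythroid genes, 13 were higher and 0 lower in HPC (median 3.17). Of 13 megakaryocyte genes 6 were higher and 0 lower (median 2.02), with ITGB3 at 0.56 and 74.0 and the platelet chemokine PF4 at 0.87 and 30.3. Of 14 pan-leukocyte genes 11 were higher and 0 lower (median 2.35), including ARHGDIB (12.9 to 139) and PTPN6 (4.35 to 36.3). Of 13 myeloid genes 6 were higher and 0 lower (median 2.32), including AIF1 (0.94 to 31.5) and lysozyme, LYZ (0.90 to 11.6). The myeloid list had 24 members, of which 20 were listed in the data and 13 detected. Members not detected, chosen here after their values were seen, included MPO (0.08 in HPC), AZU1 (0.13) and CD14 (0.02). Of 19 haematopoietic transcription factors 7 were higher and 0 lower (median 1.0), with GATA1 at 0.61 and 41.5, NFE2 at 5.50 and 89.7, SPI1 at 0.19 and 11.9 and MYB at 2.20 and 17.7. All 5 medians lay at percentile 100. Many members of these lists were at 1 or more only in HPC, so they could only be higher there. The random lists were not matched on this, so the percentiles partly follow from the detection rule. None of 4 detected lymphoid genes passed the rule (percentile 93.4).

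Of 25 endothelial genes, 13 were lower and 4 higher in HPC (median -1.04): SOX17 went from 26.9 to 1.45 and EGFL7 from 216 to 36.6, while MMRN1, also found in platelets, went from 0.34 to 12.9. Of 14 arterial genes 7 were lower and 2 higher, one of them EFNB2 (2.53 to 9.48), with a median of -0.87, and of 4 venous and lymphatic genes 4 were lower (median -1.53; 3 with the GC trend removed). The NOTCH pathway had 4 of 13 lower, including JAG2 (14.2 to 1.64), and 2 higher, including DLL4 (7.54 to 21.0; median -0.45). Of 10 mesenchymal transition genes 6 were lower (median -1.29; 5 with the GC trend removed), with FN1 at 545 and 90.0, and of 14 smooth muscle and mesenchyme genes 6 were lower, including TAGLN (233 to 12.4), and 1, ACTA2 (6.81 to 19.2), was higher (median -0.80). Of 6 cardiomyocyte genes 4 were lower (median -3.16) and MYL4, a myosin light chain, was higher (40.7 to 213). Of 17 epithelial junction genes 7 were lower (median -1.0), with KRT8 at 673 and 46.7.

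Of 10 BMP targets, 7 were lower and 0 higher in HPC (median -1.57), including ID1 (523 to 100.2) and SMAD7 (13.9 to 1.54). FGF and ERK targets were lower in 5 of 10 cases (median -1.15; 6 with the GC trend removed), activin and NODAL targets in 2 of 10 (median -0.84) and WNT targets in 1 of 9 (median -0.81; 2 with the GC trend removed), with none higher in these 3 lists. Pluripotency genes were lower in 5 of 20 cases (median -0.77), with POU5F1 at 112 and 15.4, primitive streak genes in 2 of 14 (median -0.66), early mesoderm genes in 6 of 22 (median -0.93) and definitive endoderm genes in 2 of 8 (median -0.79). In some of these lists few members stood at 5 or more in HEP as deposited, and only those could be called lower. They were SMAD7 and TDGF1 (activin and NODAL), SP5 (WNT), SP5 and WNT3 (primitive streak) and APOA1 and SOX17 (definitive endoderm). All of them were lower. Antigen presentation genes were lower in 3 of 8 cases, with TAP1 at 12.4 and 0.91, while B2M was higher (74.1 to 226; median -1.25). The immediate early and heat shock list had 2 of 14 members higher and 2 lower, with a median of -0.35 (percentile 1.57). This call did not hold with the GC trend removed (4 higher, 2 lower, percentile 13.4) or with a pseudocount of 0.1 (2.69). Within the central 95% lay the sort antigens (percentile 65.5) and the trophoblast and amnion (16.8), HOXB (4.05), DNA methylation (63.3), glycolysis (38.4) and housekeeping (96.9) lists. The cell cycle list did too (percentile 12.0), but lay at percentile 0.40 with the GC trend removed.

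By the rule of size 530 genes were higher and 630 lower in HPC than in HEP, against 467 and 615 with the GC trend removed. The share of higher genes, 45.7%, was 35.3% with each library rescaled to a common total (735 higher, 1345 lower). Rescaling without mitochondrial, ribosomal protein and globin genes gave 61.8% (919 and 568). That step returns each library to its own sum, not to a common scale. It raises HPC more than HEP, since ribosomal protein and globin genes made up more of the sum in HPC.

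From end to end, between hESC and HPC, 822 genes were higher and 2778 lower, against 1118 and 1163 with the GC trend removed. The share of higher genes was 22.8% as deposited, 34.0% with median-of-ratios scaling (1096 higher, 2132 lower), 47.9% with upper quartile scaling (1523 and 1658), 34.2% with each library rescaled to a common total (1637 and 3151) and 49.0% with the GC trend removed. Of 20 pluripotency genes 17 were lower and 0 higher (median -4.29), and of 17 epithelial junction genes 14 were lower (median -2.42). Of 19 haematopoietic transcription factors 14 were higher (median 3.68), and of 19 erythroid genes 12 were higher and 1 lower (median 4.20, with 0 lower once the GC trend was removed). Of 25 endothelial genes 16 were higher and 0 lower (median 2.36), so that most of them stayed above their hESC level in HPC. The other 9 did not pass the rule, such as EGFL7 (32.9 to 36.6). Cell cycle genes were lower in 17 of 24 cases (median -1.20, percentile 0.08; 7 of 24 lower, median -0.54, percentile 0.30, with the GC trend removed). Of the 31 lists with 3 or more detected members, 15 lay outside the central 95% of random lists from hESC to MES, 19 from MES to HEP, 23 from HEP to HPC and 22 from hESC to HPC, of 124 list medians computed. Of the 22, the definitive endoderm and the smooth muscle and mesenchyme lists lay within the central 95% over members at 5 or more (percentiles 88.4 and 78.0). The housekeeping list did so with the GC trend removed (95.3). The immediate early and heat shock list did so with either (97.0 and 94.9), as did the NOTCH pathway (96.3 and 92.1), also with median-of-ratios scaling (96.6). The DNA methylation and antigen presentation lists lay within the central 95% as deposited (6.8 and 25.3), but outside it with the GC trend removed (2.4 and 1.94).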

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

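The gene lists, the rule of size, the rule for named genes and the alternatives were set before the data were examined, except rescaling to a common total and removal of the GC trend, which were chosen afterwards. No paired analysis was possible because each group is 1 library, and for the same reason no replicate could be left out. The 48 named differences, the 8 largest per direction of the 3 successive comparisons, kept their direction. They stayed past the rule under a pseudocount of 0.1, median-of-ratios scaling, upper quartile scaling and removal of the GC trend. They were chosen for their size, the smallest being -3.49 (ZDHHC22), so this was nearly fixed in advance and says nothing of smaller differences. Counts are given from hESC to MES, MES to HEP, HEP to HPC and hESC to HPC, against 1322, 3032, 1160 and 3600 as reported. A stricter rule lowered them by construction: a pseudocount of 5 gave 723, 1878, 669 and 2362 genes, a minimum of 20 gave 536, 1118, 493 and 1458, and a fold of 4 gave 395, 1016, 307 and 1471. Without a minimum the first was 2005. Rescaling to a common total, which changes the ratios between libraries, the genes that reach the minimum and the weight of the pseudocount, gave 2158 from hESC to MES and 2080 from HEP to HPC. With the GC trend removed 1504 genes differed from MES to HEP and 2281 from hESC to HPC, and the least similar pair was hESC and HPC (rho 0.843) in place of hESC and HEP. From hESC to MES a fold of 4 left 274 higher and 121 lower, 69.4% higher. Genes counted for 1 library, 1202 in all, numbered 311 at a fold of 4 (95 in hESC, 91 in MES, 29 in HEP, 96 in HPC) and 542 at a minimum of 20 (219, 122, 99 and 102). For hESC they numbered 304 with median-of-ratios scaling and 241 with the GC trend removed. Of 124 list medians, 112 kept their side of the central 95% with the GC trend removed, 122 with median-of-ratios scaling and 116 with a pseudocount of 0.1. Over members at 5 or more, 104 kept their side, 7 moved inside, 4 moved outside and 1, given next, changed sign. Lists with too few such members had no median there. The smooth muscle and mesenchyme median from hESC to HPC, 0.44 as reported, was -0.15 over members at 5 or more, where it lay within the central 95%. Apart from the stricter rules, the cause was not tested. Depth is unknown, so low values limit the lists whose members stand mostly under 5.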

Other observations

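The genes in this and the next paragraph were chosen after their values were seen, except the list results. No HOXA gene was detected: the highest value of 11 was 0.37, while HOXB genes reached 7.52, the value of HOXB4 in HPC. PTPRC, which encodes the leukocyte antigen CD45, was at 0.04 in HPC, where SPN stood at 24.4 and VAV1 at 43.0. LIN28A, an RNA-binding protein of early development, stood at 442 in hESC and still at 98.7 in HPC, in the library with the fetal globins. The beta-like globin genes HBE1, HBG1, HBG2, HBD and HBB summed to 2785 in HPC. The alpha-like genes HBA1, HBA2 and HBZ summed to 139, a ratio of 20, with HBB at 8.32 and HBZ at 17.3. HBM, another alpha-like gene, stood at 2.05 and was left out of the sum. Near-identical globin genes share reads, and GC content differs between the groups (64.5% for HBA1, 51.0% for HBG2). Whether the ratio reflects the transcripts in the cells was not tested.

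Of the ligand and receptor pair of apelin, APLNR stood at 344 in MES, 250 in HEP and 15.6 in HPC, and APLN at 0.02, 22.0 and 0.22. The collagen IV genes COL4A1 and COL4A2 were highest in HEP, with COL4A1 at 43.0 in MES, 158 in HEP and 38.3 in HPC, and COL4A2 at 40.5, 209 and 68.9. ISG15, a ubiquitin-like protein induced by interferon, stood at 33.1 in hESC, 20.9 in MES, 397 in HEP and 938 in HPC.

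Of the tests that follow, 5 were chosen only after the results they bear on had been seen: both of proliferation, that of S phase and both of cells carried over between sorts. The values of the second test of proliferation and of the second test of carry-over, a count, were known when their bounds were set. The differences from MES to HEP followed transcript GC content. Transcript length argued against itself as the source, since rho with GC content stayed at 0.69 or more within each of 5 classes of length. Within 7 protein complexes, whose members are made together, the slope on GC content had a median 1.28 times that of all genes, which is consistent with a GC bias of the sequencing libraries, and a lowest value of 0.87 per 10 points, which argues against slower proliferation as the only source. A contribution of proliferation stays open: the low-GC members of the cell cycle list lay below its high-GC members by -1.50 (medians -1.50 and -0.003), but the slope of all genes alone gives -1.19. A difference in the cells that acts on transcripts by their base composition stays open and was not tested, because each population is 1 library.

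Histone cluster genes were mostly higher in HEP than in hESC, 51 of 65, with a median log2 difference of 0.38. More cells in S phase is argued against by the S phase list, whose median was -0.74 with the GC trend removed. A GC bias cannot be told apart from other sources here: with the trend removed the median was 0.20, under the bound of 0.25 set beforehand, but 42 of 65 genes were still higher and the quartiles, -0.21 and 0.84, spanned it, a criterion added after the median was seen. More RNA without a poly(A) tail may also contribute. The gap of 0.50 to the 7 polyadenylated histone variants was, unrounded, just under the bound set beforehand. These variants went both ways with the GC trend removed (3 of 7 higher, quartiles -0.55 and 0.86), so the gap cannot decide and this stays open.

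Endothelial genes remained in HPC at a median of 0.42 times their HEP value (quartiles 0.26 and 0.91), over the 21 of 25 detected members at 5 or more in HEP, a choice that leaves out members low in HEP and higher in HPC, such as MMRN1. If HEP cells carried into the HPC sort were the source, few abundant HEP genes could stand below that ratio. The 5th percentile over 1977 genes at 20 or more in HEP was 0.26, which lies between the bounds set for the test, so this test left carry-over open. A count argues against carry-over as the only source: 23 of the 1977 genes lay under 0.105, which is 0.25 times the endothelial ratio (22 of 1973 under the same multiple with the GC trend removed), although HEP cells would bring all their abundant transcripts. A smaller share of carried-over cells, or of HEP cells low in these genes, stays open.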
